A study of Homo sapiens with 12 samples.

How the data were processed

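The study measured gene expression in the multiple myeloma cell line MM.1S on 12 Affymetrix arrays, 1 per sample, with 3 samples in each of 4 groups (control, F, PD and FPD). Groups, replicate numbers, doses and the 24 h of exposure were taken from the labels. For the F group the title and the shared treatment protocol give only the letter F. Its treatment label gives 1 nM filanesib with 10 nM dexamethasone. Total RNA was isolated and biotin-labelled, per the labels' protocols. No batch or scan date was used here.

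The deposited values are log2 expression values made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA corrects the background, normalizes the arrays to a common distribution and summarises the probes of a transcript cluster on the log2 scale. Versions and further settings were not given in the sources used here. The values ran from 1.61 to 13.75, and array medians lay between 4.23 and 4.27, so a change in the total amount of RNA per cell would not show. RMA compresses low signals, so fold changes of weakly expressed genes are understated. No detection p-values were used, and values near the array medians cannot be separated from background with certainty.

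Gene names came from the platform annotation of the table's rows. Of 53617 rows, 16098 (30.02%) had exactly 1 gene symbol, 0 had several and 37519 had none. Rows without a symbol are unnamed here and entered no comparison of genes. All 14884 entrez identifiers were found in the RefSeq gene table of assembly GRCh38.p14, which was used for names only. A total of 779 genes had more than 1 row, and the row with the highest mean over the 12 arrays stood for the gene. The 14884 genes so obtained were tested without a filter on expression.

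A linear model of group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom per gene), so that the 4 groups shared 1 estimate of the spread per gene. The 5 pairwise comparisons were PD against control, F against control, FPD against control, FPD against PD and FPD against F. A further contrast, FPD minus PD minus the difference of F and control, measured the departure from additivity on the log2 scale. Tests were two-sided, p-values were adjusted by the method of Benjamini and Hochberg over all genes, and an adjusted p under 0.05 was called a change. In the text "rose", "fell", "higher" and "lower" in counts of genes refer to this threshold, fc is the fold change, and a log2 change is the difference of group means.

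The 17 gene lists, the rule for named genes and the alternative settings other than those named as added had been fixed before the data were examined. The lists were glucocorticoid-induced genes, interferon-stimulated genes, MHC class I presentation, mitosis and spindle genes, DNA replication genes, replication-dependent histones, p53 target genes, the BCL2 family, the unfolded protein and integrated stress response, plasma cell identity genes, ribosome biogenesis and MYC targets, cholesterol synthesis, NF-kB target genes, B cell genes, T cell markers, myeloid markers, and stromal and epithelial markers. Members were matched by symbol, and an older symbol was translated only where it is not the current symbol of another gene, a correction made after results of the lists had been seen. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 15 lists tested, and again with an estimated correlation, and members passing the threshold were counted over all genes and over the list alone. The MHC class I list had 4 measured members and was described without a test. None of the 50 histone genes had a named row, and these were not analysed here. The mean of a list in each array was compared between groups by an exact permutation test, for which 3 arrays against 3 give a smallest two-sided p of 0.1.

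The genes named in the text follow a fixed rule. For each pairwise comparison it takes the 10 highest and 10 lowest log2 changes among called genes whose 2 groups of arrays do not overlap (5 and 5 for the departure from additivity). It adds the 2 highest and 2 lowest members of each list, and 17 genes fixed by name. Of these 13 were measured (KIF11, CRBN, IKZF1, IKZF3, IRF4, MYC, BCL2L11, BAX, MCL1, BCL2, FKBP5, CCNB1 and CDK1) and 4 were not analysed here. Immunoglobulin, T cell receptor, small RNA and unnamed loci were left out of the ranked names. Genes behind a count of 5 or fewer were named outside the rule, after their values were seen. NEK2, CD68, ERAP2 and similar members are named as extremes of their lists.

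The correlation of PD and F responses was set beside 100 simulations of unchanged groups that shared controls. The model was tested on simulated data made from the real genes' means and spreads with 50 genes changed at each of 4 sizes. In every pairwise comparison it recovered 98% to 100% of genes changed by a log2 of 1, 60% to 70% of those changed by 0.5 and 2% to 16% of those changed by 0.3, with 4 to 9 false calls among 140 to 147. A comparison with fewer true changes than were simulated has a stricter adjusted threshold, so these shares overstate its power. A list shifted by 0.3 in simulated data was called, and 0 of the 14 other lists were. Genes were drawn independently of each other in these simulations. In the real data the estimated correlation was 0.141 for the mitosis list and 0.211 for the ribosome biogenesis list. The simulation thus does not show how often the preset correlation calls unchanged lists of correlated genes.

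The other settings tried were the replicate number as a block, genes above the median mean (5.39), all rows of the table, the mean of a gene's rows, a repeated quantile normalization, arrays set to 1 median, an intensity trend in the variance, array weights, a fit to the compared arrays alone, a fold change of at least 1.5, an estimated correlation for lists, and leaving out each array in turn. Added after the data had been examined were the filanesib effect averaged over both backgrounds, the rows with no gene symbol, the side-by-side view of comparisons that share no arrays, and separate control arrays for the correlation of PD and F responses. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.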

Results

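Gene expression was profiled in MM.1S, an established human multiple myeloma cell line that is sensitive to glucocorticoids, after 24 h of treatment. A total of 12 Affymetrix arrays were analysed, 3 in each of 4 groups. Control cells received vehicle. PD cells received 500 nM pomalidomide, a drug that binds cereblon and directs the transcription factors IKZF1 and IKZF3 to degradation, together with 10 nM dexamethasone, a synthetic glucocorticoid. F cells received 1 nM filanesib, an inhibitor of the kinesin spindle protein encoded by KIF11. FPD cells received filanesib with pomalidomide and dexamethasone at these doses. The treatment label gives the F group 10 nM dexamethasone as well, while its title and the shared protocol give only the letter F. Whether it received dexamethasone is thus left open, and it is called the F group throughout. Values are the deposited log2 RMA expression values. Array medians lay between 4.23 and 4.27, and arrays of a group correlated with each other at r = 0.988 to 0.992 across the 53617 rows of the table. No pair of arrays held identical values. Of the rows, 16098 carried exactly 1 gene symbol, and 14884 distinct genes were tested. The number of arrays, 3 per group, limits the precision of every value below. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The genome build was not given in the sources used here, and no gene positions are stated.

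The response to pomalidomide plus dexamethasone was determined by comparing PD with control. DDIT4, an inhibitor of mTOR signalling that glucocorticoids induce (transcript cluster 16705961), showed the highest increase, from 5.99 ± 0.08 to 10.45 ± 0.01 (mean log2 ± SD, n = 3 per group; fc = 22.0, limma, Benjamini-Hochberg adjusted p = 8.74e-15). Expression of IRF4, a transcription factor on which myeloma cells depend (transcript cluster 17004167), fell from 11.44 ± 0.06 to 10.21 ± 0.13 (log2 change -1.23, limma adjusted p = 2.2e-07), and MYC fell from 10.65 ± 0.04 to 10.14 ± 0.07 (log2 change -0.52, limma adjusted p = 0.000574). Genes of DNA replication and of ribosome biogenesis were lower almost as whole groups, while glucocorticoid-induced and interferon-stimulated genes were higher. In all, 1018 genes were higher and 1284 lower in PD than in control, of which 92 and 51 changed at least 2-fold. With the arrays quantile normalized again, 1157 were higher and 1081 lower, so which direction held more genes depended on the scaling.

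After DDIT4, the strongest increases in PD were those of the leukotriene receptor CYSLTR1 (log2 change 2.69, fc = 6.47), the small GTPase RRAS (2.69, fc = 6.43), the surface glycoprotein CD109 (2.48, and 1.39 as the mean of its rows), the secreted WNT antagonist DKK1 (2.42), the fatty acyl-CoA reductase FAR2 (2.38), the calpain family member CAPN6 (2.37), the membrane endopeptidase MME (2.27), the pro-apoptotic BCL2 family member BMF (1.92, fc = 3.77) and PDGFRL (1.88). Adjusted p-values of these genes ranged from 3.76e-09 for MME to 2.51e-07 for PDGFRL (limma, Benjamini-Hochberg). The strongest decreases were those of the chemokine CXCL10 (-2.44, 5.43-fold lower), CBLN2 (-2.23, 4.69-fold lower), LGALS17A (-1.90), the RNA polymerase III subunit POLR3G (-1.59), ANKRD37 (-1.56), ADAM23 (-1.53), the transcription factor MYB (-1.42), the serine synthesis enzyme PSAT1 (-1.39), CABLES1 (-1.36) and the transcription factor ETS1 (-1.33). LGALS17A is a pseudogene, and its probes can share signal with related galectin genes. BMF had 2 rows, and its change was 1.64 at the lowest over the alternative settings. The naming rule required that the 3 PD arrays lie apart from the 3 control arrays in each of the ranked genes, so that separation is no further evidence.

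Of 26 measured DNA replication genes, 24 fell in PD and none rose (mean log2 change -0.67, camera adjusted p = 5.57e-23, and 0.00608 with an estimated correlation). The cell cycle transcription factor E2F1 (-1.20) and the origin licensing factor CDC6 (-1.16) fell most, and RRM2 had a log2 change of -0.22 (limma adjusted p = 0.0706, and 0.0369 among the genes above the median mean). Adjusted over the list alone, all 26 were lower. Of 25 measured genes of ribosome biogenesis and MYC targets, MYC itself included, 22 fell and none rose (mean -0.65, camera adjusted p = 5.77e-22, and 0.0158 with an estimated correlation), led by LYAR (-1.31) and RRP12 (-0.97). Adjusted over the list alone, 24 were lower. Of 17 measured genes of cholesterol synthesis, 9 fell and none rose, also when adjusted over the list alone (mean -0.36, camera adjusted p = 7.17e-07, and 0.0166 with an estimated correlation). SQLE (-0.84) and HMGCS1 (-0.83), enzymes of the pathway, had the lowest values.

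Among 22 measured glucocorticoid-induced genes, DDIT4 included, 10 rose and 1 fell in PD (mean log2 change 0.55, median 0.21, camera adjusted p = 1.23e-05, and 0.0334 with an estimated correlation). Among the genes above the median mean, the median of the list was 0.70. That filter used the mean over all 12 arrays, so members raised in PD and FPD could pass it through those arrays. The 0.70 is thus no independent measure of the response. The member that fell was MT2A (-0.51, limma adjusted p = 0.0286), a call lost without control replicate 1 (limma adjusted p = 0.139). FKBP5, a co-chaperone of the glucocorticoid receptor, rose from 5.57 ± 0.03 to 7.06 ± 0.12 (fc = 2.81, limma adjusted p = 8.14e-07), and PIK3IP1, an inhibitor of PI3 kinase, rose by 1.70 (fc = 3.24). Adjusted over the list alone, 10 were higher and 4 lower. Of 31 measured interferon-stimulated genes, 11 rose and 1, HERC5 (-0.52), fell (mean 0.29, camera adjusted p = 9.65e-06, and 0.0334 with an estimated correlation). The exonuclease gene ISG20 rose by 1.37 (fc = 2.58). IFIT3 rose by 1.24 from 3.82 ± 0.34 (n = 3), a control level below the array medians and not shown to be above background. In this list 12 were higher and 1 lower when adjusted over the list alone. CXCL10, itself interferon-inducible and outside the list, fell.

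**Figure D1:**
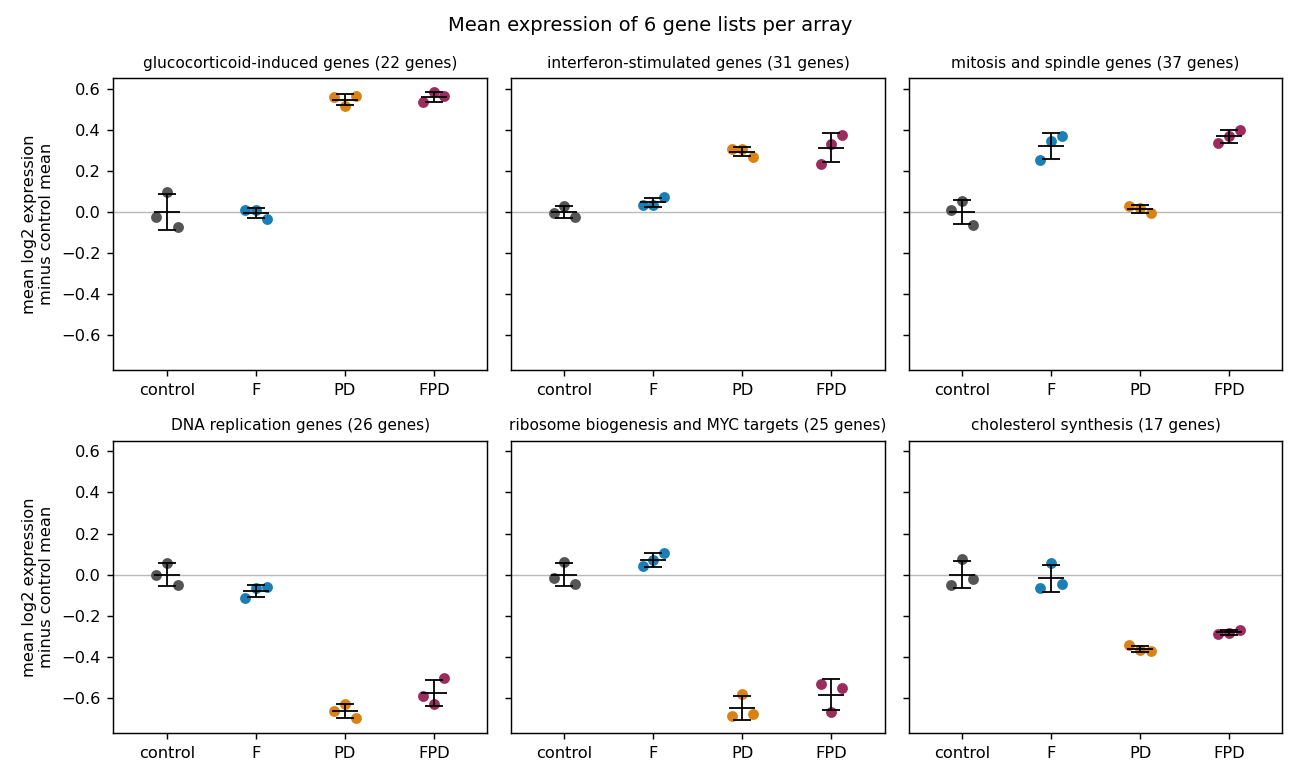
Mean log2 expression of 6 gene lists in each of the 12 arrays, minus the mean of the control arrays, where points are arrays, horizontal bars are group means and error bars are SD (n = 3 per group). The glucocorticoid list lies at 0.547 in PD and 0.561 in FPD and at -0.006 in F, and the mitosis list lies at 0.322 in F and 0.368 in FPD and at 0.014 in PD.

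The other lists did not pass the test as groups in PD. Adjusted over each list alone, 5 p53 target genes were higher and 3 lower, with 4 and 2 in the BCL2 family, 3 and 8 in the stress response, 2 and 3 among plasma cell genes and 5 and 3 among NF-kB target genes. Of 37 mitosis and spindle genes, 2 were higher and 1 lower (mean 0.014, camera adjusted p = 0.698), and CCNB2, which encodes a mitotic cyclin, was among the higher (0.52, limma adjusted p = 0.000495). Adjusted over the list alone, 1 was higher. Of 18 BCL2 family genes, 4 rose and 1 fell (camera adjusted p = 0.232). BMF and the mitophagy receptor gene BNIP3L (0.80) rose and the pro-apoptotic BID (-0.43) fell, while BAX (-0.13, limma adjusted p = 0.385) and BCL2 (0.10, limma adjusted p = 0.673) did not pass the test. Without PD replicate 1 the value of BCL2 was -0.023 (limma adjusted p = 0.938), and without PD replicate 3 that of BAX was -0.059 (limma adjusted p = 0.766). The anti-apoptotic MCL1 rose by 0.36 (limma adjusted p = 0.0108), a call that was lost without control replicate 1 (limma adjusted p = 0.0553). BCL2L11, which encodes BIM, had a log2 change of -0.32 (limma adjusted p = 0.0599). It passed the test without control replicate 1 (limma adjusted p = 0.0144), without PD replicate 1 (limma adjusted p = 0.0432), and among the genes above the median mean (limma adjusted p = 0.0292). Of 18 genes of the unfolded protein and integrated stress response, 8 fell, led by PSAT1 and the degradation factor SEL1L (-0.95), and 2 rose, with DDIT4 the highest (camera adjusted p = 0.166). The median of this list was -0.18 and its mean 0.025.

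Of 14 plasma cell identity genes, 2 fell in PD, IRF4 and the surface antigen gene SLAMF7 (-0.48), and 1, IKZF1, rose (camera adjusted p = 0.698, median 0.0037, mean -0.047). The pomalidomide receptor gene CRBN (0.33, limma adjusted p = 0.0255) and IKZF1 (0.33, limma adjusted p = 0.0273) rose slightly. CRBN lost its call without control replicate 2 (limma adjusted p = 0.0682), control replicate 3 (0.0721), PD replicate 1 (0.0678) or PD replicate 3 (0.0865), and over all rows of the table (0.0562). IKZF1 lost it without control replicate 1 (limma adjusted p = 0.112), control replicate 2 (0.0768) or PD replicate 1 (0.122), over all rows (0.0643) and in the compared arrays alone (0.0744). IKZF3 lay at 4.18 ± 0.17 in control and 4.59 ± 0.40 in PD (n = 3), close to the array medians (limma adjusted p = 0.196). Of 15 p53 target genes, 4 rose and 2 fell (camera adjusted p = 0.248), with TP53I3 (0.81) the highest. Of 13 NF-kB target genes, 4 rose and 2 fell (camera adjusted p = 0.698, median -0.081, mean 0.029). In that list CFLAR (1.03), an inhibitor of death receptor signalling, and BIRC2 (0.51) rose, and the chemokine CCL3 (-1.16) and PLEK (-0.60) fell.

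Among lists of other cell types in PD, 1 of 10 B cell genes fell, the complement receptor CR2 (-1.23, limma adjusted p = 3.09e-06), and none rose (camera adjusted p = 0.456). Of 9 myeloid markers 1 rose, CD68 (camera adjusted p = 0.646), from 8.62 ± 0.01 to 10.24 ± 0.13 (n = 3 per group; fc = 3.09, limma adjusted p = 1.31e-08). CD68 encodes a lysosomal glycoprotein, and the myeloid markers CD163 (3.46 ± 0.20) and MPO (4.30 ± 0.15) lay at low levels in PD (n = 3). None of 10 T cell markers (camera adjusted p = 0.698) and none of 9 stromal and epithelial markers (camera adjusted p = 0.92, median -0.025, mean 0.017) changed. Only 4 members of the MHC class I presentation list were measured, and the list was not tested. Of these ERAP2, a peptide-trimming enzyme, rose by 1.03 (fc = 2.05, limma adjusted p = 1.52e-06), and B2M had a log2 change of 0.033 (limma adjusted p = 0.875), or 0.36 as the mean of its rows (limma adjusted p = 0.115).

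**Figure D2:**
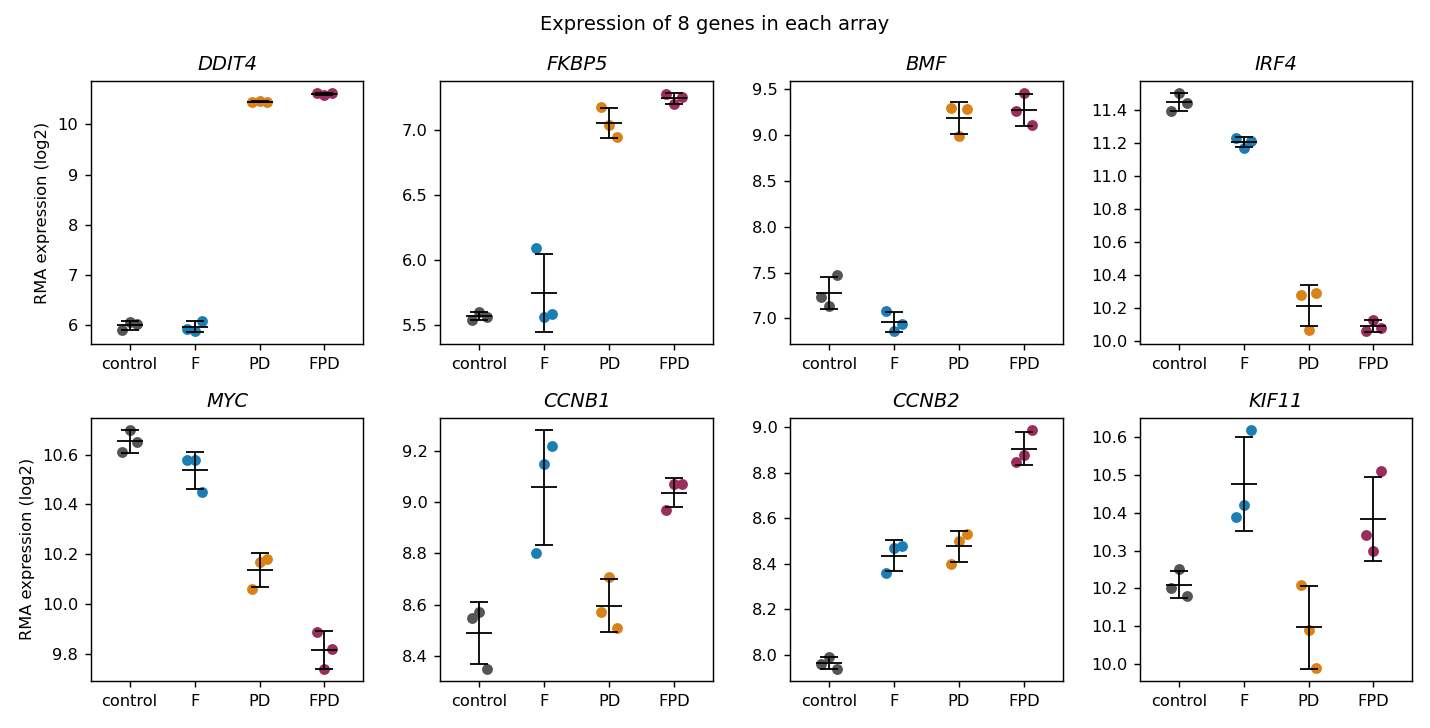
RMA expression (log2) of 8 genes in each array by group, where points are arrays, horizontal bars are means and error bars are SD (n = 3 per group), and each panel has its own vertical scale, which does not start at 0. DDIT4, FKBP5 and BMF are higher and IRF4 and MYC lower in PD and FPD than in control, and the mitotic cyclin gene CCNB2 lies at 7.96 in control, 8.44 in F, 8.48 in PD and 8.91 in FPD.

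The effect of the filanesib arm was determined by comparing F with control. Genes of mitosis and the spindle moved upwards together. All 37 measured members had a positive log2 change (mean 0.32, median 0.30), the list passed the test (camera adjusted p = 1.41e-39, and 0.00331 with an estimated correlation), and its mean over the members was higher in each of the 3 F arrays (0.251 to 0.369) than in any control array (-0.063 to 0.055). The exact permutation test of this mean gave the smallest two-sided p that 3 arrays against 3 allow, p = 0.1. None of the members passed the test over all genes, and 29 were higher when adjusted over the list alone. The log2 change of the spindle protein gene HMMR was 0.60 and that of CCNB1, the cyclin of mitotic entry, 0.57 (limma adjusted p = 0.198 for both over all genes). For KIF11, which encodes the target of filanesib (transcript cluster 16707468), levels were 10.21 ± 0.04 in control and 10.48 ± 0.13 in F (n = 3; log2 change 0.27, limma adjusted p = 0.702), and for CDK1 the log2 change was 0.44 (limma adjusted p = 0.606).

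Over all genes, 1 was higher and none lower in F than in control, the microRNA locus MIR4771-1 (log2 change 0.87, limma adjusted p = 0.0147), named because the count was that small. Its control level of 3.67 lay below the array medians and was not shown to be above background. An unadjusted p under 0.05 was reached by 895 genes, with 744.2 expected by chance. In simulated data of the same size, 68% of genes changed by a log2 of 0.5 and 2% of those changed by 0.3 were recovered in this comparison. Those data held 141 calls, many of them from larger changes, which loosens the adjusted threshold. With 1 call in the real comparison, these shares overstate what could be detected here. Changes of the size seen in the mitosis list were thus mostly not detectable gene by gene. The call of MIR4771-1 was lost without control replicate 1 (limma adjusted p = 0.0924), control replicate 2 (0.162), F replicate 1 (0.0735), F replicate 2 (0.121) or F replicate 3 (0.0782), and 2 genes were called without control replicate 3. With the replicate number as a block, it was lost too (limma adjusted p = 0.0623), and 910 genes had an unadjusted p under 0.05.

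None of the genes that led the PD response passed the test in F. DDIT4 lay at 5.97 ± 0.11 in F against 5.99 ± 0.08 in control (n = 3). The 22 glucocorticoid-induced genes had a mean log2 change of -0.0061 (camera adjusted p = 0.9), with FKBP5 at 0.18 (limma adjusted p = 0.902). The change of this list in PD exceeded that in F by 0.553 (95% interval 0.460 to 0.646). FKBP5 differed between the F arrays, with 6.09 in F replicate 1 and 5.56 and 5.58 in the others. The 31 interferon-stimulated genes had a mean of 0.046 (camera adjusted p = 0.333), and IRF4 a log2 change of -0.24 (limma adjusted p = 0.702). In the BCL2 family BMF (-0.32, limma adjusted p = 0.719) and MCL1 (-0.13, limma adjusted p = 0.903) did not pass the test (camera adjusted p = 0.207 for the list). Replication genes lay slightly lower (mean -0.080, camera adjusted p = 0.0272) and ribosome biogenesis genes slightly higher (mean 0.071, camera adjusted p = 0.0337), but neither passed with an estimated correlation (adjusted p = 0.639 for both). The replication call was also lost without control replicate 1 (camera adjusted p = 0.0613), control replicate 2 (0.329) or F replicate 1 (0.295). The ribosome call was lost without control replicate 1 (camera adjusted p = 0.136), control replicate 3 (0.197), F replicate 1 (0.0572) or F replicate 3 (0.219). Adjusted over the list alone, 2 replication genes and no ribosome biogenesis gene passed the test. MCM5 (-0.33) and GINS2 (-0.35) had the lowest values among replication genes, and GAR1 (0.34) and PNO1 (0.34) the highest among ribosome biogenesis genes. No other list passed the test in F.

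The response to all 3 drugs was determined by comparing FPD with control. It combined the changes described for PD with a higher expression of mitosis genes. Of the 37 mitosis and spindle genes, 20 rose and none fell (mean log2 change 0.37, camera adjusted p = 3.62e-16, and 0.021 with an estimated correlation), led by CCNB2 (0.95, fc = 1.93) and the kinase gene NEK2 (0.69, fc = 1.62), and 30 were higher when adjusted over the list alone. CCNB1 rose from 8.49 ± 0.12 to 9.04 ± 0.06 (n = 3, limma adjusted p = 0.0035). DDIT4 again rose most (4.62, fc = 24.6, limma adjusted p = 5.05e-15), followed by RRAS (2.68), CAPN6 (2.49), CD109 (2.48, and 1.36 as the mean of its rows), FAR2 (2.45), CYSLTR1 (2.43), DKK1 (2.17), SLFN5 (2.13), MME (2.08) and BMF (2.00). CBLN2 (-2.50), CXCL10 (-2.16), LGALS17A (-1.68), ANKRD37 (-1.66), CCL3L1 (-1.54), MYB (-1.52), CCDC110 (-1.46), PSAT1 (-1.37), POLR3G (-1.36) and IRF4 (-1.35, 2.56-fold lower) fell most. The chemokine gene CCL3L1 is nearly identical to CCL3, so the 2 cannot be told apart by hybridisation with certainty. The change of BMF was 1.46 at the lowest over the alternative settings. In all, 1080 genes were higher and 876 lower.

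Replication genes fell in FPD (18 of 26 lower, none higher, mean -0.58, camera adjusted p = 6.07e-21, and 0.00871 with an estimated correlation), with E2F1 (-1.05) and MCM6 (-1.04) the lowest. Ribosome biogenesis genes and MYC targets fell as well (22 of 25 lower, none higher, mean -0.59, camera adjusted p = 2.32e-21, and 0.0165 with an estimated correlation), with LYAR (-0.93), RRP12 (-0.86) and MYC (-0.83, limma adjusted p = 8.57e-06) among them. Of the 17 cholesterol synthesis genes 6 fell (mean -0.28, camera adjusted p = 3.42e-05, and 0.0264 with an estimated correlation), with SQLE (-0.72) and MSMO1 (-0.66) the lowest. Adjusted over each list alone, 24 replication, 24 ribosome biogenesis and 7 cholesterol synthesis genes were lower. Glucocorticoid-induced genes rose as a list (8 higher, 1 lower of 22, camera adjusted p = 1.87e-05, and 0.0264 with an estimated correlation). Their mean log2 change was 0.56 and their median 0.11, with 13 positive and 9 negative values. FKBP5 lay at 7.25 ± 0.04 in FPD (fc = 3.20, limma adjusted p = 2.33e-07). The member that fell was SGK1 (-0.395, limma adjusted p = 0.0185), a call lost without control replicate 2 (limma adjusted p = 0.0976). Interferon-stimulated genes rose too (10 higher, 1 lower of 31, mean 0.31, camera adjusted p = 1.17e-06, and 0.0264 with an estimated correlation), with ISG20 (1.43) and IFIT3 (1.39) among them. Adjusted over each list alone, 9 glucocorticoid-induced genes were higher and 3 lower, and 12 interferon-stimulated genes were higher and 1 lower. MCL1 rose by 0.40 (limma adjusted p = 0.00663). CD68 (1.46), ERAP2 (1.04) and CFLAR (1.17) rose, and SLAMF7 (-0.54), CCL3 (-1.29) and CR2 (-0.96) fell. No other list passed the test in FPD.

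The contribution of filanesib on top of pomalidomide and dexamethasone was determined by comparing FPD with PD. Mitosis and spindle genes were higher as a list. All 37 had a positive log2 change (mean 0.35, median 0.36, camera adjusted p = 8.37e-37, and 0.00426 with an estimated correlation). The mean over the list lay between 0.336 and 0.397 in the FPD arrays and between -0.007 and 0.030 in the PD arrays (exact permutation test, two-sided p = 0.1, the smallest possible). None of them passed the test over all genes, and 33 were higher when adjusted over the list alone. The kinesin gene KIF14 (0.57, limma adjusted p = 0.0839) and PRC1 (0.52, limma adjusted p = 0.0566), which encodes a protein of the spindle midzone, had the highest values. PRC1 passed the test without PD replicate 1 (limma adjusted p = 0.0446), and both passed among the genes above the median mean (limma adjusted p = 0.0389 for KIF14 and 0.0321 for PRC1). CCNB1 (0.45, limma adjusted p = 0.206) and KIF11 (0.28, limma adjusted p = 0.423) did not pass.

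Over all genes, 5 were higher and none lower in FPD than in PD, all named because the count was small. They were EBLN2 (1.06, fc = 2.09, limma adjusted p = 0.022), the microRNA loci MIR4521 (0.82) and MIR4771-1 (0.71, limma adjusted p = 0.0363, with 3.55 in PD, below the array medians), LOC100288637 (0.72), and PARPBP (0.66, fc = 1.58, limma adjusted p = 0.0325), which encodes a regulator of homologous recombination. EBLN2 derives from an integrated bornavirus gene. MIR4521 lay at 8.88 ± 0.22 in control, 9.12 ± 0.18 in F, 7.85 ± 0.10 in PD and 8.67 ± 0.10 in FPD (n = 3). Its mean in FPD was thus higher than in PD but not higher than in control. Without PD replicate 2 or 3 or FPD replicate 1 or 3 no gene was called, 3 were called without FPD replicate 2 and 15 without PD replicate 1, and none when the rows of a gene were averaged. With the replicate number as a block all 5 calls were lost (limma adjusted p = 0.0503 for EBLN2, MIR4521, LOC100288637 and PARPBP, and 0.0628 for MIR4771-1), and 1295 genes had an unadjusted p under 0.05. The glucocorticoid-induced (mean 0.014, camera adjusted p = 0.844) and interferon-stimulated genes (mean 0.021, camera adjusted p = 0.831) did not differ detectably between FPD and PD. MYC had a log2 change of -0.32 (limma adjusted p = 0.251) and IRF4 of -0.12 (limma adjusted p = 0.732). Replication genes lay slightly higher (mean 0.089, camera adjusted p = 0.0474), which did not hold with an estimated correlation (adjusted p = 0.591), nor without PD replicate 1 (camera adjusted p = 0.221), PD replicate 3 (0.224), FPD replicate 1 (0.0661) or FPD replicate 3 (0.444). Ribosome biogenesis genes (mean 0.065, camera adjusted p = 0.187) passed the test without PD replicate 2 (camera adjusted p = 0.00961) or FPD replicate 2 (camera adjusted p = 0.012).

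**Figure D3:**
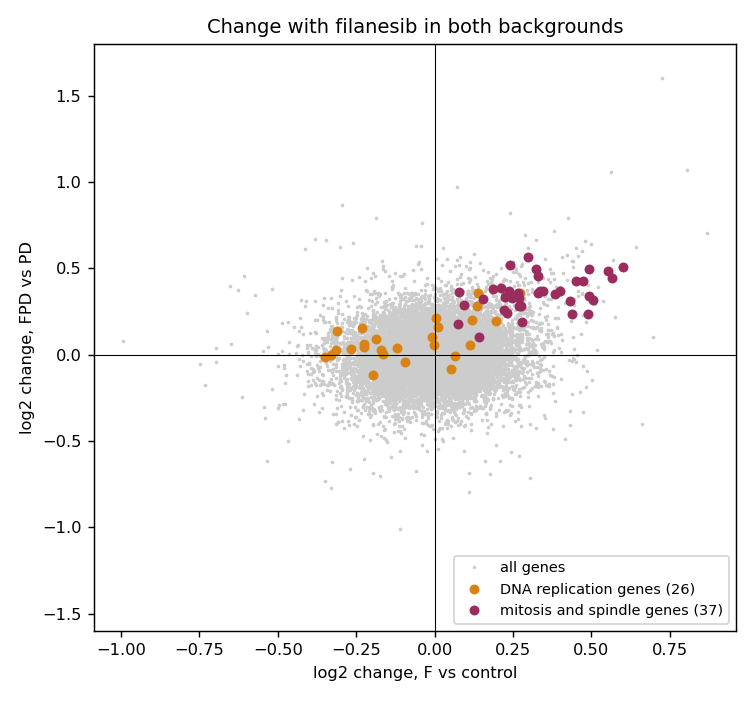
Log2 change of each gene in F against control (horizontal axis) and in FPD against PD (vertical axis), which share no arrays, with all 14884 genes in grey, the 37 mitosis and spindle genes in purple and the 26 DNA replication genes in orange. All 37 mitosis genes lie above 0 on both axes.

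The contribution of pomalidomide, with dexamethasone if the F group had none, on top of filanesib was determined by comparing FPD with F. DDIT4 rose from 5.97 ± 0.11 to 10.61 ± 0.02 (n = 3, log2 change 4.65, limma adjusted p = 4.59e-15), and CAPN6 (2.62), FAR2 (2.58), CD109 (2.39, and 1.36 as the mean of its rows), CYSLTR1 (2.38), BMF (2.32), RRAS (2.23), DKK1 (2.11), SLFN5 (1.95) and the ribonuclease gene ZC3H12A (1.95) followed. CXCL10 (-2.46), CBLN2 (-2.35), CCL3L1 (-1.58), LGALS17A (-1.51), PSAT1 (-1.48), ANKRD37 (-1.46), POLR3G (-1.46), CCDC110 (-1.36), SYCP3 (-1.36) and CD200R1 (-1.25) fell most. IRF4 (-1.12, limma adjusted p = 5.51e-07) and MYC (-0.72, limma adjusted p = 3.34e-05) fell, and MCL1 (0.53, limma adjusted p = 0.000754) and IKZF1 (0.59, limma adjusted p = 0.000559) rose. The change of BMF was 1.63 at the lowest over the alternative settings. In all, 1117 genes were higher and 988 lower in FPD than in F.

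Replication genes (21 of 26 lower, mean -0.50, camera adjusted p = 6.63e-18, and 0.0112 with an estimated correlation) and ribosome biogenesis genes (22 of 25 lower, mean -0.66, camera adjusted p = 3.04e-24, and 0.0112 with an estimated correlation) fell between F and FPD. The glucocorticoid-induced genes rose as a list (8 higher, 2 lower of 22, mean 0.57, median 0.215, camera adjusted p = 1.03e-05, and 0.0412 with an estimated correlation). The lower members were MT2A (-0.528, limma adjusted p = 0.0268) and SGK1 (-0.392, limma adjusted p = 0.0184). Both calls were lost over all rows of the table (limma adjusted p = 0.102 and 0.0562). Interferon-stimulated genes (9 of 31 higher, mean 0.27, camera adjusted p = 9.86e-05) and cholesterol synthesis genes (7 of 17 lower, mean -0.26, camera adjusted p = 0.000167) passed the test with the preset correlation but not with an estimated correlation (adjusted p = 0.0566 and 0.0502). The BCL2 family (mean 0.23, camera adjusted p = 0.095) passed without FPD replicate 3 (camera adjusted p = 0.0401). Adjusted over each list alone, 25 replication, 24 ribosome biogenesis and 8 cholesterol synthesis genes were lower, and 8 glucocorticoid-induced and 10 interferon-stimulated genes were higher. The 37 mitosis genes did not pass as a list (mean 0.045, camera adjusted p = 0.306), with 4 higher and 1 lower, both over all genes and over the list alone. Of these CCNB2 was 0.47 higher and MAD2L1, a gene of the spindle checkpoint, 0.60 lower in FPD (log2 change -0.60, limma adjusted p = 0.000662).

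Comparisons that share no arrays were set side by side. The changes in PD against control and in FPD against F correlated across genes at Pearson r = 0.781 and Spearman rho = 0.592. PD against control and FPD against F shared 711 higher and 717 lower genes, with none in opposite directions. Independent lists of these sizes would share 76.4 and 85.2. If the F group received dexamethasone, FPD against F measures pomalidomide alone, and F against control measures filanesib with dexamethasone. The filanesib effects (F against control and FPD against PD) correlated across genes at r = 0.135 and rho = 0.097. Genes are not independent replicates, and no p-value is attached to these correlations. This side-by-side view was added after the data had been examined.

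Whether PD and F shared a response was tested across genes. Their log2 changes against the same controls correlated at Pearson r = 0.138. Simulated unchanged groups that shared controls gave 0.482 to 0.514. These simulations held no change in PD, where 2302 genes were called against control. Such changes widen the spread of the PD values and lower a correlation whether or not F shares them. The simulated and observed correlations are thus not comparable, and no conclusion about a shared response is drawn from them. The covariance was 0.00539 against a simulated mean of 0.0071, a difference of -0.00171. No gene was called in both, but with 1 gene called in F the overlap could hardly differ from 0 (independent lists would share 0.0684 higher genes, and simulations a mean of 0.01), so it does not bear on the question. With separate controls for PD and F, 1 array for either and the other 2 for the other, the 6 arrangements gave correlations of -0.142 to 0.000 (mean -0.062) and a mean covariance of -0.00336. The positive correlation was thus not seen without shared controls. The arrangements reuse the same arrays, genes are not independent replicates, and no p-value is attached. This arrangement of the controls was added after the data had been examined. The correlation rose to 0.239 without control replicate 1 and 0.235 without control replicate 2, and was 0.061 among the genes above the median mean.

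Whether the effect of filanesib depended on the presence of pomalidomide and dexamethasone was tested as the difference between FPD minus PD and F minus control. No gene passed the test (limma, smallest adjusted p = 0.888), and 833 genes had an unadjusted p under 0.05, with 744.2 expected by chance. The mitosis list showed no detectable difference (mean 0.031, camera adjusted p = 0.663), nor did the glucocorticoid-induced genes (mean 0.020, camera adjusted p = 0.851). For MYC the difference was -0.20 (limma adjusted p = 0.896), for BCL2L11 0.30 (limma adjusted p = 0.888) and for KIF11 0.012 (limma adjusted p = 0.992). Of the 26 replication genes, 22 had a positive difference (mean 0.17, camera adjusted p = 0.000165), which did not hold with an estimated correlation (adjusted p = 0.544). Cholesterol synthesis genes (mean 0.099, camera adjusted p = 0.236) passed without F replicate 2 (camera adjusted p = 0.0227). If the F group had also received dexamethasone, its effect would enter this difference.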

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

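The difference in the replication list was tested as planned, while its interval over the arrays was added and the rows without a gene symbol were examined only after the results had been seen. The difference between the filanesib effects in the 2 backgrounds passed the test for the 26 DNA replication genes with the preset correlation but not with an estimated one, and no member passed the test. The median of the difference was 0.163 on the log2 scale, higher in the presence of pomalidomide and dexamethasone (mean change -0.080 in F against control, with a 95% interval of -0.171 to 0.010, and 0.089 in FPD against PD, with an interval of -0.002 to 0.180). The test of the difference (camera adjusted p = 0.000165) ranged from 6.35e-06 to 0.544 over the alternatives, the highest being that with an estimated correlation. Over the array means of the list the difference was 0.169 (95% interval 0.041 to 0.298), which does not compare the list with other genes.

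Rows without a gene symbol, which entered no comparison of genes, also held called changes. Of the 37519 such rows, 29 were higher and 1 lower in F than in control, and 86 were higher and 1 lower in FPD than in PD (limma, adjusted p under the threshold). The comparisons share no arrays, and 20 rows were called in both, where independent lists would share 0.0696. Row 16810884 had a log2 change of 2.19 in F against control and 2.46 in FPD against PD, with means of 3.67, 5.86, 3.79 and 6.26 in control, F, PD and FPD. Row 16656943 had changes of 1.76 and 2.14, with a mean of 3.77 in PD. The control and PD levels of the former row and the PD level of the latter lay below the array medians and were not shown to be above background, so the sizes of these changes are uncertain.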

How the results depend on the processing

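Separate control arrays for PD and F were the only alternative given here that was chosen after the results had been seen, and no called value of a gene or list reversed under any alternative. The call of 1 gene in F against control became 0 with the replicate block and among genes above the median mean, 4 with the intensity trend and 32 over all rows of the table, and 0 to 2 when an array was left out. The 5 genes of FPD against PD became 0 with the replicate block and with the mean of a gene's rows, 8 in the compared arrays alone, 12 with array weights, 20 among genes above the median mean, 32 with the intensity trend, 94 over all rows, and 0 to 15 when an array was left out. All rows include those without a symbol; for the other settings the cause was not tested. A fold change of at least 1.5 left 772 genes in PD against control, 643 in FPD against control and 681 in FPD against F, by its construction. With the replicate block and no fold threshold the counts of these comparisons were 2277, 1916 and 2057, beside 2302, 1956 and 2105 without the block. Whether the replicate numbers pair the samples stayed open. The deviations of 18 pairs of equally numbered arrays correlated at -0.256 to 0.158, with 5 pairs over 0.1, and 9 of 18 correlated best with their own number. Each F array did so with FPD (r = 0.117, 0.083 and 0.124), and no control array did so with PD (r = -0.256, -0.006 and -0.068). With only 3 arrays in a group, a part of such matches would arise by chance. The departure from additivity called 0 genes under every alternative run. The correlation of PD and F responses was 0.061 among genes above the median mean and 0.109 to 0.239 when an array was left out, and the cause was not tested. It turned to -0.062 with separate control arrays, which removes the covariance that shared controls add. Of the 22 list results called among 90, 6 lost the call with an estimated correlation and 3 when some array was left out (11 of 138 values). Of the 173 called results of named genes among 491, 35 lost the call when some array was left out (133 of 1038 values). Of the values of uncalled results without an array, 4 of 492 for lists and 13 of 2334 for named genes gained it. Among values of named genes not called, 107 changed sign under an alternative and stayed uncalled. Among genes above the median mean the median of the glucocorticoid list was 0.703 in PD against control (0.205 with all genes), and as the mean of its rows the change of CD109 was 1.391 (2.485 with the row of highest mean). The filter on the mean included the PD and FPD arrays, so it could favour list members raised there. Low signals, such as 4.18 for IKZF3 and 2.73 for FCRL5 in control, lie near or below the array medians, where signal over background limits what can be detected.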

Other observations

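The average of the filanesib effects over both backgrounds, and all tests of explanations below except those of gene abundance and of other splits of the arrays, were chosen after the results had been seen. In this average (F against control and FPD against PD), limma called 57 genes higher and 7 lower. Of the 57, 19 belonged to the mitosis list of 37 genes and 0 to the replication list. Since the average was chosen after the mitosis list had been seen higher in both comparisons, these 19 are not further evidence of its direction. Of the protein-coding genes outside the list, those with the highest log2 changes were EBLN2 (0.81), CCDC18 (0.57), PARPBP (0.57), TROAP (0.56) and C18orf54 (0.53). The lower genes included KRT37 (-0.54), GCSAM (-0.47) and PLK2 (-0.37). Of the 57, 5 were microRNA loci. These genes were named after their values were seen.

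A hypothesis for the higher mitosis list is that inhibition of the spindle motor holds a part of the cells in mitosis. The abundance of the list's genes does not account for it, since 100% of 10000 random lists matched on mean expression had a lower median change (0.345 for the list, -0.007 to 0.057 for the middle 95% of the random lists). A larger share of cycling cells as the whole cause would raise replication genes like mitosis genes, but the average change of the replication list was 0.00431 (95% interval -0.060 to 0.068) against 0.338. That average joins -0.080 (-0.171 to 0.010) in F against control and 0.089 (-0.002 to 0.180) in FPD against PD, each below the interval of the mitosis list there (0.234 to 0.410 and 0.265 to 0.441), and a smaller contribution in FPD is not excluded. The difference of both lists, 0.334 (95% interval 0.289 to 0.378), follows from these values and is no separate test, so cells held in mitosis stay open as an explanation, with no measurement of cell cycle phase analysed here.

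The glucocorticoid-induced genes, higher in both groups that received pomalidomide with dexamethasone, did not pass the test in F. The mean log2 change of the list was -0.006 (95% interval -0.099 to 0.087) against 0.547 in PD. Against the F arrays being untreated cells stands the mitosis list, which was 0.322 higher than in control (95% interval 0.234 to 0.410). The title of the F group gives only the letter F, and its treatment label gives dexamethasone. An absence of dexamethasone in F and a rise of the list that needs pomalidomide cannot be told apart. The change of the list in F is the pattern itself, and 0 arrays were labelled with dexamethasone alone or with pomalidomide alone.

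Counts of called genes were set beside those of other splits of the same arrays, of which 6 arrays allow 10, too few for a share under 0.05. For PD against control 1 of the 10 splits, the real one, gave as many genes (2302, and at most 0 in the others), as it did for FPD against control (1956, at most 0), for FPD against F (2105, at most 0) and for FPD against PD (5, at most 2). Every other split mixes arrays of both groups, so a real difference enters the spread and lowers its count. The low counts of the other splits are thus partly set by their construction. For F against control 2 of the 10 splits gave as many (1, at most 1 in the others). The departure from additivity called 0 genes, a count that all 100 splits drawn must reach (at most 1 in the others), so the splits decide nothing there.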
